A study of Bos taurus with 32 samples.

How the data were processed

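Total RNA of 32 left adrenal cross-sections from Bos taurus steers was extracted with TRIzol, made into biotin-labelled cRNA and hybridised to a bovine gene array of 1 colour, per the labels' protocols. The submitters' processing notes name GCOS 1.2 and Partek. The probe set summary method, the normalisation and the genome build are not given in the sources used here. The values analysed are the authors' deposited table of log2 signal per probe set, which runs from 1.23 to 14.6. Its array medians lie between 6.78 and 6.86, so the arrays had been made comparable before deposit, and any difference in total RNA between glands would no longer show. No value was missing and no 2 arrays were identical. The first principal component held 13.0% of the variance. Scan dates, array batches, slaughter order and pasture are not in the labels used here, so none of them could be tested as a batch. Signal over background is not known for the deposited values. Several named genes, among them OR7E203, ZBBX, DPPA3 and OR5D62P, have group means under 5, toward the lower end of the scale.

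Each array was placed in its group by its label, and the animal numbers in the labels run across the groups without repeating. No steer or number is shared between groups, so no pairing was fitted. The 8 steers of a group are separate animals by their numbers, and the p-values of single genes are set against the spread between them.

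Probe sets were named from the array's platform table. Of 26773 probe sets, 18550 carry 1 gene symbol, 595 carry several and 7628 are unnamed here, and genes were named only from the first kind. They name 18087 genes, 416 of them by more than 1 probe set. Of their gene identifiers, 17996 were found in a RefSeq gene table of the assembly ARS-UCD2.0, used for names only, so no coordinates are given. For gene values and gene lists the probe set with the highest mean signal stood for its gene. The steroid genes STAR, found only on a probe set shared with other genes, and CYP11B1 were not analysed here.

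All tests used R 4.3.3 with limma 3.58.1 on the log2 values, with 1 mean per group over all 32 arrays, a shared spread moderated by eBayes, and Benjamini-Hochberg adjustment over the 26773 probe sets, called at an adjusted p of 0.05. Because the values are log2 already, no pseudocount or floor was used. In all, 7 contrasts were tested: the 2 main effects, the interaction, and the 4 differences between single groups. A main effect is the mean of 2 group differences, and the interaction is the TE minus NTE difference in MIX less that in ISe. Intervals are 95% intervals of the moderated fit.

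Before the data were examined, 34 gene lists were fixed for the functions and cell types of cortex and medulla, selenium metabolism, stress, immunity and connective tissue. Lists were tested with camera and its preset correlation of 0.01, and again with an estimated correlation and with fry, which asks only whether a list's members move on balance in 1 direction. The preset correlation treats list members as nearly independent, so its camera p does not measure the spread between steers alone. None of the lists called with the preset correlation passed with an estimated correlation or with fry in any of the 7 contrasts. A list score is the mean over members of the log2 signal less the gene's mean over all arrays. The genes named were also fixed by rule: per contrast up to 10 genes past the threshold in each direction and, where fewer than 5 passed in a direction, the rest of 5 by the smallest unadjusted p, then up to 4 members of each list with the smallest p, and a set of adrenal and selenium genes whether or not they passed. PCBD1, SULT1A1, PDGFRB, COL6A1, MBP, LEP, BOLA-DQA5 and CIDEA are named where they passed over their list alone. That adjustment was made within 1 list and 1 contrast at a time. It was not made over the 34 lists and 7 contrasts, so some such genes are expected by chance.

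The code was tested on simulated data in which 200 of 26773 probe sets were changed by a log2 difference of 0.25, 0.5 or 1. For the comparison of TE with NTE within ISe, 65.5% were recovered at 0.5 and 94.5% at 1. The simulation draws probe sets independently, whereas real genes vary together. It also plants 200 changes of equal size at once. The adjusted threshold is stricter when fewer probe sets change, so recovery would then be lower.

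The alternatives tried were a quantile normalisation of the deposited values, a filter on dim probe sets, array weights, trended and robust moderation, no moderation, an adjusted p of 0.10, 1 probe set per gene, the chromaffin marker score as a covariate, single-pair fits of 16 arrays, and leaving out each of the 32 arrays. The first principal component and the interferon score as covariates, and quantile normalisation for single named genes, were added after seeing the data. Fits with several residual principal components as covariates were also looked at. They raised the number of endophyte calls, but components taken from the residuals of the same model make its test too liberal by construction, so those fits were dropped and no result rests on them. Some random labels had been looked at before the splits of the endophyte counts were set. Labels were redrawn at random, 100 splits per contrast with the real one included, keeping the other factor in place for the main effects. For the interaction all 32 labels were shuffled over the 4 groups, so those splits stand for no effect of any kind, not for no interaction alone. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.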

Results

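Gene expression was measured in the left adrenal gland of 32 beef steers, with 1 array per steer. The adrenal gland holds a cortex that makes steroid hormones and a medulla whose chromaffin cells make catecholamines, and the labels state that RNA came from cross-sections through the middle of the gland. The steers formed a factorial design of 4 groups of 8, labelled ISeTE, ISeNTE, MIXTE and MIXNTE. As background to this work, ISe stands for an inorganic selenium supplement, MIX for a blend of inorganic and organic selenium, TE for tall fescue carrying a toxic endophyte (a fungus that makes ergot alkaloids) and NTE for fescue with a non-toxic endophyte. The design asks whether the adrenal transcriptome differs with the endophyte, with the form of selenium, and whether either depends on the other. The 32 arrays gave 26773 probe sets each, with array medians from 6.78 to 6.86 on the log2 scale and correlations between arrays from 0.969 to 0.987. The number of steers limits the precision of every value below.

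The first comparison set the 16 TE steers against the 16 NTE steers over both selenium forms. No gene passed the test, and the genes with the smallest p are given here as values. ARF2, a small GTPase of Golgi vesicle traffic, had a mean log2 signal of 9.01 in NTE and 8.46 in TE, a difference of -0.55 (95% interval -0.75 to -0.34), and 16 of the 16 TE steers lay below the NTE mean. RBM3, a cold-inducible RNA-binding protein, differed by -0.49 (-0.68 to -0.30) and GPR63, a G protein-coupled receptor, by -0.51 (-0.71 to -0.31), with 15 and 16 of the 16 TE steers below the NTE mean. NPR2, the receptor of C-type natriuretic peptide, differed by 0.26 (0.15 to 0.36), with 15 of the 16 TE steers above the NTE mean, and its other probe set gave 0.17. These 4 genes shared the smallest adjusted p of limma, 0.0966.

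TFPI, an inhibitor of the start of blood clotting, had the largest difference among the named genes of this comparison, at -0.74 (95% interval -1.05 to -0.43, adjusted p = 0.134 with limma), and LOC782385 differed by -0.54. CCDC185 and the galectin gene LGALS4 were each 0.30 higher in TE, TMEM203 was 0.19 higher and the olfactory receptor gene OR2Q2 was 0.56 higher, with adjusted p from 0.134 to 0.172. With limma, 0 of the 26773 probe sets passed an adjusted p of 0.05, and 2625 had an unadjusted p under 0.05, of which 1378 were higher and 1247 lower in TE, where 1338.65 are expected by chance. When only the 13386 probe sets above the median level were tested, ARF2, NPR2, GPR63 and RBM3 passed limma, each with an adjusted p of 0.0353. This filter was among the alternatives tried, and no random splits were drawn with it. Without it, 5 of the other random splits of the endophyte labels called a probe set.

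**Figure D1:**
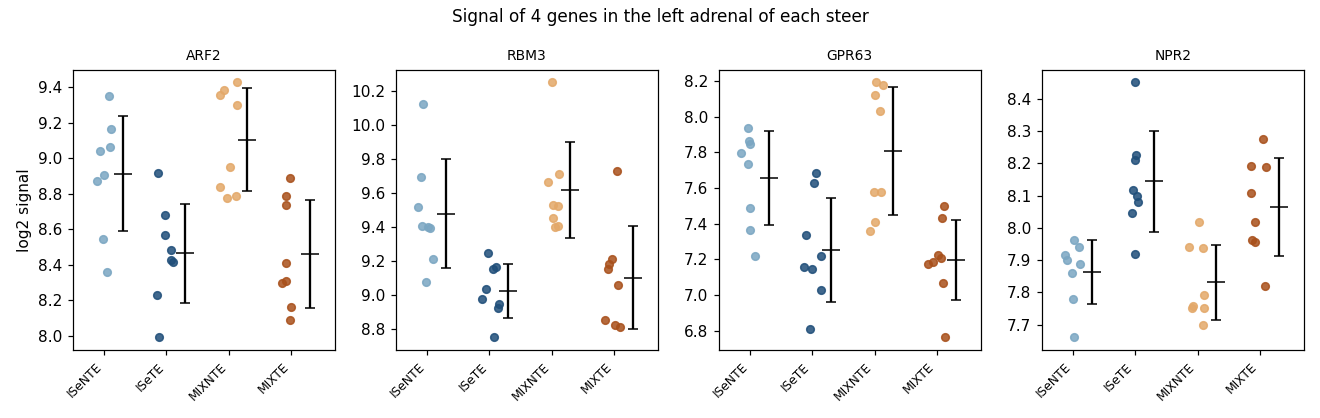
The log2 signal of ARF2, RBM3, GPR63 and NPR2 in each steer, with 8 points per group and the mean and SD as black bars. The group means of ARF2 were 8.91 and 9.10 in the NTE groups and 8.46 in both TE groups, and those of NPR2 were 7.86 and 7.83 in the NTE groups and 8.14 and 8.07 in the TE groups.

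Among gene lists, the one that joins targets of the transcription factor NRF2 with general antioxidant enzymes had the smallest list p, lower in TE. Of 27 measured members, 21 were lower and 6 higher, 7 had an unadjusted p under 0.05, all of them lower, and none passed alone. The members with the smallest p were GCLM, a subunit of the enzyme that opens glutathione synthesis (-0.17), PRDX2, a peroxiredoxin (-0.14), SLC7A11, the cystine importer (-0.46), and MGST1, a glutathione transferase (-0.35). The list passed camera with its preset correlation, with an adjusted p of 0.00073. It did not pass with an estimated correlation, where the adjusted p was 0.40.

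The fibroblast and capsule markers also tested lower in TE, with 16 of 22 members lower and a camera adjusted p of 0.0033, against an adjusted p of 0.62 with an estimated correlation. Adjusted over the list alone, 5 members fell: fibronectin FN1 by 0.31, the collagen genes COL1A1 by 0.26, COL6A3 by 0.26, COL1A2 by 0.24 and COL6A1 by 0.22. The receptor gene PDGFRB rose by 0.19, and none of the 6 passed over all probe sets. Adjusted over the list alone, SULT1A1, a sulfotransferase that conjugates phenols, also fell, by 0.46, in the xenobiotic metabolism list, and PCBD1, which recycles the cofactor of tyrosine hydroxylase, fell by 0.28 in the catecholamine list.

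Cell cycle genes (19 of 27 lower, among them CDK1 at -0.31 and PCNA at -0.28), macrophage markers (15 of 21 lower, with lysozyme LYZ at -0.68), oxidative phosphorylation genes (40 of 57 lower) and interferon response genes (26 of 27 lower) passed camera in the same direction, with adjusted p of 0.0089, 0.011, 0.016 and 0.020. With an estimated correlation their adjusted p were 0.62, 0.80, 0.80 and 0.86. No member of the interferon list had an unadjusted p under 0.05. Its genes were high in 8 steers that stood apart, 4 in TE and 4 in NTE, and the call was lost when any 1 of 11 arrays was left out (adjusted p up to 0.70). Higher in TE were the chromaffin markers (22 of 24 higher, with the granule protein gene CHGA at 0.16), cholesterol synthesis genes (16 of 18), Schwann and sustentacular cell markers (11 of 13) and glucocorticoid response genes (11 of 17, with ERRFI1 at 0.37 and ZBTB16 at 0.29), with camera adjusted p of 0.0089, 0.022, 0.032 and 0.032. Their adjusted p with an estimated correlation were 0.80, 0.85, 0.62 and 0.80. With the chromaffin marker score as a covariate, 3 of the 9 endophyte calls outside the chromaffin and catecholamine lists remained. The cholesterol synthesis score of 1 NTE steer, ISeNTE 5, stood apart at -0.78 and the cell cycle score of another, ISeNTE 11, at 0.48, and each call was lost without that steer. When 1 array was left out, the calls of cholesterol synthesis and glucocorticoid response were each lost for 13 of the 32 arrays (adjusted p up to 0.22 and 0.15), Schwann markers for 9, macrophage markers for 4, oxidative phosphorylation for 3, chromaffin markers for 2 and cell cycle for 1.

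Among the genes of the adrenal hormones, the cortical enzymes below and the ACTH receptor differed little with the endophyte. The cortical enzymes CYP11A1 (-0.01, 95% interval -0.13 to 0.11), HSD3B1 (0.04, -0.02 to 0.11), CYP17A1 (-0.04, -0.16 to 0.08) and CYP21A2 (0.01, -0.10 to 0.13) and the ACTH receptor MC2R (-0.03, -0.19 to 0.13) did not pass. The sign of CYP11A1 turned when the deposited values were quantile normalised, to 0.0029. The medullary enzymes TH, DBH and PNMT differed by -0.02, 0.18 and 0.04, and the prolactin receptor PRLR by 0.28 (-0.16 to 0.73). None of these passed. A small difference is not shown for DBH or PRLR, and is not claimed for TH or PNMT. Within MIX the interval of DBH ran from -0.09 to 0.66. The steroid hormone synthesis list had 8 of 18 members higher and 10 lower (camera adjusted p = 0.88).

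**Figure D2:**
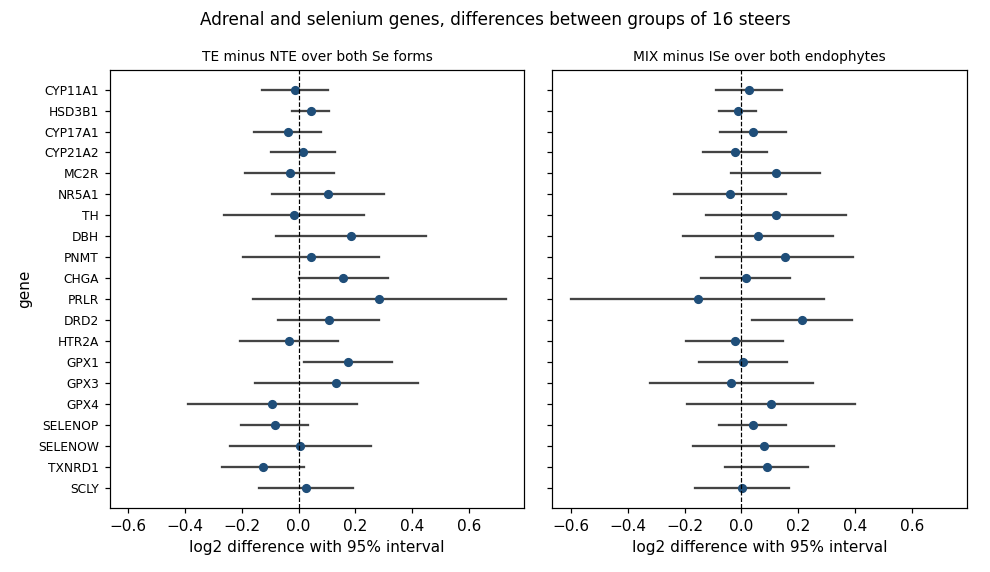
Log2 differences of 20 adrenal and selenium genes with their 95% intervals from limma, between 16 TE and 16 NTE steers on the left and between 16 MIX and 16 ISe steers on the right. In the left panel the interval leaves out 0 for CHGA and GPX1, and in the right panel for DRD2, and none of these passed the adjusted test.

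In simulated data with the spread of these arrays, 80.5% of 200 changed probe sets were recovered for the endophyte comparison at a log2 difference of 0.5 and 29% at 0.25. At the smaller size most changed probe sets were missed. These shares hold for 200 probe sets changed at once. With fewer changes recovery would be lower, so a lone difference of 0.5 could be missed.

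The second comparison set the 16 MIX steers against the 16 ISe steers over both endophytes. The genes with the smallest p were APMAP, an adipocyte membrane protein gene, at 0.20 (95% interval 0.11 to 0.29), TMEM218 at 0.20, ZBBX at 0.28, LRRC66 at 0.29 and the olfactory receptor gene OR7E203 at 0.35. On the lower side stood DPPA2 at -0.21 and DPPA3 at -0.30, both genes of early embryonic cells, CIDEA, a lipid droplet protein gene, at -0.21, KIZ at -0.25 and OR9S23B at -0.53. None passed: with limma the smallest adjusted p was 0.9999, and 0 of 26773 probe sets were called. At an unadjusted p under 0.05 there were 657 probe sets (289 higher and 368 lower in MIX), fewer than the 1338.65 expected by chance.

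No selenoprotein gene passed the test between the selenium forms. The wider intervals below, as for GPX3 and GPX4, do not show that the differences were small. Of 24 measured selenoproteins 17 were higher and 7 lower in MIX, with a median log2 difference of 0.01, none with an unadjusted p under 0.05 (camera adjusted p = 0.58). The selenium carrier gene SELENOP differed by 0.04 (95% interval -0.08 to 0.16), the glutathione peroxidase genes GPX1 by 0.01 (-0.15 to 0.16), GPX3 by -0.04 (-0.32 to 0.25) and GPX4 by 0.10 (-0.19 to 0.40), and TXNRD1, a thioredoxin reductase gene, by 0.09 (-0.06 to 0.23). The list of selenocysteine synthesis and incorporation, which also holds genes of other steps such as GSR and LRP8, had 9 of 12 members higher (camera adjusted p = 0.29). The dopamine receptor gene DRD2 was 0.21 higher in MIX (0.04 to 0.39), in 12 of the 16 MIX steers above the ISe mean, with an adjusted p of 0.9999 in limma.

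With the preset correlation, camera called 5 of the 34 lists between the selenium forms. Lower in MIX were cell cycle genes (21 of 27 lower, with CENPF at -0.23), interferon response genes (26 of 27), immediate early genes (19 of 24) and endothelial markers (17 of 21, with ESAM at -0.14), with adjusted p of 0.013, 0.034, 0.034 and 0.041. Heat shock genes were higher (16 of 19, with HSPB8 at 0.22, adjusted p = 0.039). With an estimated correlation the adjusted p of these lists lay between 0.78 and 0.80. Of the 8 steers with high interferon genes 5 were ISe and 3 MIX, and the interferon call was lost when any 1 of 17 arrays was left out (adjusted p up to 0.40). The endothelial call was lost for 21 of the 32 arrays, heat shock for 18, immediate early genes for 11 and cell cycle for 2, among them ISeNTE 11, and the 5 calls ranged from 0 to 8. Adjusted over the list alone, the adipocyte marker CIDEA fell, by 0.21.

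In simulated data 84.5% of 200 changed probe sets were recovered for the selenium comparison at a log2 difference of 0.5, and 21% at 0.25. As for the endophyte, recovery would be lower with fewer changed probe sets.

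The third comparison asked whether the endophyte difference depends on the selenium form, as the TE minus NTE difference in MIX less that in ISe. IGFBP5, which binds insulin-like growth factors, had the smallest p: its mean log2 signal was 7.13 in ISeNTE, 7.40 in ISeTE, 7.68 in MIXNTE and 7.19 in MIXTE, an interaction of -0.76 (95% interval -1.11 to -0.41). MCL1, an inhibitor of cell death, had an interaction of 0.35 (0.14 to 0.55), and THAP10 one of -0.48. The others with the smallest p in either direction were LOC100336443 (0.82), DNAI3 (0.41), MIR2446 (0.98), TMCO5A (0.32), OR5D62P (-1.31), OR2T13 (-0.59) and CYLC1 (-0.51). Apart from OR2T13 (5.80), their mean log2 signals over all arrays lay between 3.56 and 4.31, toward the lower end of the scale. None passed: the smallest adjusted p of limma was 0.9998, 0 of 26773 probe sets were called, and 792 had an unadjusted p under 0.05, of which 399 were positive.

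Camera with the preset correlation called 9 lists for the interaction, all positive. The immediate early genes, which respond to stimulation within minutes, had 21 of 24 members positive, with IER2 at 0.58, FOSL1 at 0.77 and FOSB at 0.43 (adjusted p = 6.6e-07). Their mean score was -0.15 ± 0.25 in MIXNTE and 0.07 ± 0.16 in MIXTE, and 0.06 ± 0.21 in ISeNTE and 0.02 ± 0.23 in ISeTE (SD, n = 8). Cell cycle genes had 20 of 27 members positive, with TPX2 at 0.43 and BUB1B at 0.53 (adjusted p = 3.2e-05). The cell cycle score of ISeNTE 11 stood apart at 0.48, and without that steer the adjusted p was 0.0044, the highest when each array was left out in turn. With an estimated correlation the adjusted p of the immediate early and cell cycle lists was 0.44 each.

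**Figure D3:**
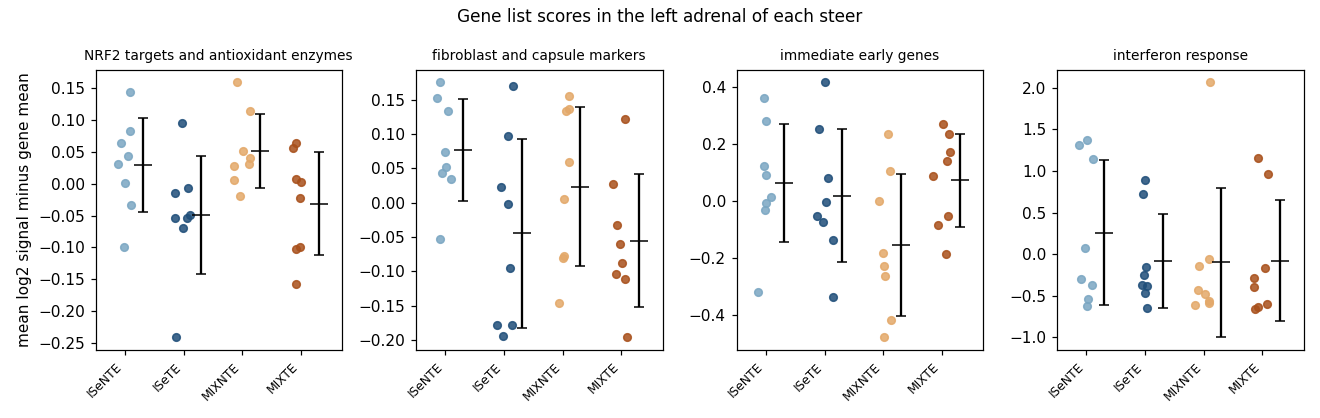
Scores of 4 gene lists in each steer, as the mean over members of the log2 signal less the gene's mean over the 32 arrays, with 8 points per group and the mean and SD as black bars. The NRF2 and antioxidant score averaged 0.03 and 0.05 in the NTE groups and -0.05 and -0.03 in the TE groups, and the interferon score reached 2.06 in a single MIXNTE steer.

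The other lists called for the interaction were heat shock genes (15 of 19 positive, DNAJB1 at 0.64), unfolded protein response genes (20 of 24, XBP1 at 0.37), interferon response genes (25 of 27), MHC class II genes (11 of 13, BOLA-DQA5 at 0.76), T and NK cell markers (18 of 26, CD3D at 0.70), glucocorticoid response genes (15 of 17) and chromaffin markers (18 of 24, SYT1 at 0.48). Their camera adjusted p ran from 0.0058 to 0.036, and with an estimated correlation each was 0.80. Interferon genes were high in 3 ISeNTE, 2 ISeTE, 1 MIXNTE and 2 MIXTE steers, and the MIXNTE steer, 25, stood apart in the scores of interferon (2.06) and MHC class II genes (0.42). The T and NK score of MIXTE 7 stood apart at 0.35, and that call was lost without it or any 1 of 5 other arrays (adjusted p up to 0.38). The chromaffin call was lost for 15 of the 32 arrays, glucocorticoid response for 9, interferon response for 8, MHC class II for 3, unfolded protein response for 2 and heat shock for 1. Adjusted over the list alone, BOLA-DQA5 had a positive and the myelin gene MBP a negative interaction (-0.54). In simulated data 28% of 200 changed probe sets were recovered for the interaction at a log2 difference of 0.5 and 82.5% at 1. Here too recovery would be lower with fewer changed probe sets.

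Within the ISe steers, TFPI differed by -0.89 between TE and NTE, HEPH, an iron-oxidising protein gene, differed by -0.35, ACSL5, an acyl-CoA synthetase gene, by -0.45 and SLC30A7, a zinc transporter gene, by -0.28, while OR5P76B differed by 0.74 and NPR2 by 0.28. None passed limma (adjusted p = 0.752 for each). Of the 26773 probe sets, 0 passed and 1550 had an unadjusted p under 0.05. Camera called 10 lists with the preset correlation, led by cell cycle genes (23 of 27 lower, CDK1 at -0.46), interferon response genes (27 of 27 lower) and fibroblast markers (15 of 22 lower, FN1 at -0.39). The smallest adjusted p with an estimated correlation was 0.31. Interferon genes were high in 3 ISeNTE and 2 ISeTE steers that stood apart from the others of their group, and the cell cycle score of ISeNTE 11 stood apart at 0.48. Adjusted over the list alone, SULT1A1 fell by 0.63 and BOLA-DQA5 by 0.54, and LEP, the leptin gene, rose by 0.29 and MBP by 0.40. Over all probe sets the adjusted p of limma was 0.776 for each.

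Within the MIX steers, GINS1, a DNA replication gene, differed by -0.38 (95% interval -0.54 to -0.22), CGN, a tight junction gene, by -0.65, ARF2 by -0.64, GPR63 by -0.61 and DUT by -0.61. HOMER1, a synaptic scaffold gene, differed by 0.55, TAF7L by 0.43 and MGAT5 by 0.39. With limma the smallest adjusted p was 0.18, for an unnamed probe set, and 0.322 for GINS1, 0 probe sets passed and 1811 had an unadjusted p under 0.05. Camera called 5 lists, with immediate early genes (22 of 24 higher, FOS at 0.48), chromaffin markers (21 of 24), glucocorticoid response genes (12 of 17, ERRFI1 at 0.58) and heat shock genes (17 of 19) higher, and the NRF2 and antioxidant genes lower (20 of 27, adjusted p = 0.0046). In the NRF2 and antioxidant list the member with the smallest p was NFE2L2, the gene of NRF2 itself. It was higher in TE, by 0.17 (95% interval 0.04 to 0.31), and the next, GCLM, was lower (-0.20). The smallest adjusted p with an estimated correlation was 0.57. Adjusted over the list alone, ERRFI1 rose and PCBD1 fell, by 0.40. Without MIXTE steer 7, GINS1 alone passed over all probe sets, with an adjusted p of 0.021.

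Between the selenium forms within TE, MUC15 differed by -0.55, CARD9, an innate immune signalling gene, by -0.31, LIMD1 by -0.37 and OR9S23B by -0.83, and MCTP1 by 0.45 and ABHD3 by 0.23. No probe set passed limma, with 692 at an unadjusted p under 0.05. Heat shock genes (15 of 19 higher in MIX), chromaffin markers (19 of 24) and unfolded protein response genes (19 of 24) passed camera with the preset correlation. The smallest adjusted p with an estimated correlation was 0.72.

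Between the selenium forms within NTE, IGFBP5 was 0.55 higher in MIX (95% interval 0.31 to 0.80, adjusted p = 0.924 with limma), CHRNB3, a nicotinic receptor subunit gene, was 0.41 higher, and BOLA-DQA5 differed by -0.67 and TAF7L by -0.42. No probe set passed, and 791 had an unadjusted p under 0.05. Camera called 7 lists with the preset correlation, all lower in MIX, led by immediate early genes (22 of 24 lower, IER2 at -0.41), cell cycle genes (23 of 27 lower, CENPF at -0.44) and interferon response genes (27 of 27 lower). Interferon genes were high in 3 ISeNTE steers and 1 MIXNTE steer that stood apart, and the cell cycle score of ISeNTE 11 stood apart at 0.48. The smallest adjusted p with an estimated correlation was 0.20, and of the 13 MHC class II genes BOLA-DQA5 fell when adjusted over the list alone.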

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

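The test of an array-wide gradient, and the tests by random splits of the counts at an adjusted p and of the endophyte count at an unadjusted p, were chosen after the result was seen, and the other tests of this part were set before their results were seen, those of the interferon list after the ISG15 values of single steers had been looked at.

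With limma no probe set passed in any of the 7 contrasts, against 2625 probe sets at an unadjusted p under 0.05 for the endophyte. With a real count of 0, every split (100 of 100) gives at least as many calls by construction, so this comparison says nothing about chance. The highest other split called 1 for the endophyte, 5 for the selenium form, 1 for the interaction, 2 within ISe, 1 within MIX, 1 within TE and 2 within NTE.

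The endophyte comparison gave 2625 probe sets at an unadjusted p under 0.05, against 1338.65 expected. If an array-wide gradient were the whole cause, the count should fall to the expected number with the first principal component as a covariate, and it was 3100 (2616 to 3569 when each array was left out). A different share of medulla in the sections would predict the same fall with the chromaffin score as a covariate, and the count was 2222 (1576 to 2714). Both counts stayed above the expected number. Random splits without a covariate ranged from 587 to 4124 probe sets, and none were drawn with one, so neither count decides on these causes. Chance cannot be excluded: 10 of 100 splits gave as many probe sets as the 2625 without a covariate, and the highest other gave 4124. An effect of the endophyte, and pasture or sampling order that followed it, stay open and untested.

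For the counts of the other contrasts at an unadjusted p, chance could not be excluded either. The selenium form gave 657 probe sets at an unadjusted p under 0.05 (99 of 100 splits gave as many, highest other 4112), the interaction 792 (82 of 100, 3437), TE against NTE within ISe 1550 (37 of 100, 4124) and within MIX 1811 (14 of 100, 4542), and MIX against ISe within TE 692 (90 of 100, 3929) and within NTE 791 (89 of 100, 4967). Random splits with several times the real count point to a structure of the samples, which may be no more than genes varying together, and its source was not tested.

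Random splits also called gene lists. With the preset correlation the endophyte gave 10 lists (19 of 100 splits gave as many, highest other 15), the selenium form 5 (62 of 100, 17), the interaction 9 (23 of 100, 14), TE against NTE within ISe 10 (19 of 100, 15) and within MIX 5 (67 of 100, 12), and MIX against ISe within TE 3 (75 of 100, 12) and within NTE 7 (52 of 100, 14). The median of the other splits was 6 lists for the endophyte, 5 for the selenium form and 5 for the interaction. For single lists of the endophyte comparison, a camera p as small came up in 2 of 100 splits for the NRF2 and antioxidant list (real p 2.2e-05, smallest other 1.4e-05), in 6 for fibroblast and capsule markers (0.00019 against 1.2e-09), in 12 for cell cycle genes (0.0010 against 4.7e-11) and in 28 for chromaffin markers (0.0011 against 1.1e-11). For cell cycle genes in the selenium comparison it was 9 (0.00038 against 4.4e-06). Of the 34 lists of the endophyte comparison, 1 (the NRF2 and antioxidant list) fell under 5 of 100, where about 1.36 are expected by chance, so chance is not excluded for it once all 34 lists are considered. In the selenium comparison and the interaction 0 lists did. Within ISe selenoproteins (4 of 100) and cell cycle genes (4) did, within MIX the NRF2 list (2), within TE the prolactin receptor and JAK-STAT list (3), and within NTE cell cycle (2) and immediate early genes (4), with the same 1.36 expected in each.

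A test of the interaction itself called 9 lists with the preset correlation, as endophyte differences that differ between selenium forms: immediate early genes (adjusted p = 6.6e-07), cell cycle (3.2e-05), heat shock (0.0058), unfolded protein response (0.0094), interferon response (0.010), T and NK cell markers (0.012), MHC class II (0.012), glucocorticoid response (0.021) and chromaffin markers (0.036). None kept this with an estimated correlation, where the smallest adjusted p was 0.44.

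The immediate early genes had the smallest p of these lists, and chance could not be excluded: 6 of 100 splits gave a camera p as small (1.9e-08, smallest other 1.3e-16), and for cell cycle genes 5 of 100 did (1.9e-06, smallest other 2.8e-08). These genes respond to handling within minutes, so the order of slaughter and sampling is a candidate explanation that no label used here records, and a true interaction stays open beside it.

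For the interferon list, 50 of 100 splits gave a camera p as small (0.0015, smallest other 5.0e-24), so chance could not be excluded, and for the endophyte 65, the selenium form 47, within ISe 42 and within NTE 47 of 100 did. If a few steers in an interferon state were the cause, the group medians should show a much smaller interaction than the group means. The interaction of the medians was 0.85 of that of the means (0.31 against 0.36), on the side against this cause. The ratio ranged from 0.31 to 1.37 when 1 array was left out. A different share of immune cells would predict that little of the interaction is left with T cell and macrophage scores as covariates. Of the interaction 0.48 was left, on the side of this explanation, with a range from 0.17 to 0.91. Both ranges take in values that each explanation predicts and values that it forbids, so neither decides, and an interaction of the treatments cannot be told apart from either.

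Of 336 groups of 8 values tested (34 list scores and 50 named genes in 4 groups), 21 held a steer far from the rest, where chance marks about 1 in 20 groups, or 16.8. Among list scores these were interferon response (2.06) and MHC class II (0.42) in MIXNTE 25, T and NK cell markers (0.35) and cytokines (0.24) in MIXTE 7, cell cycle (0.48) in ISeNTE 11, Schwann and sustentacular markers (0.26) in ISeNTE 20, and cholesterol synthesis (-0.78) in ISeNTE 5. The prolactin receptor PRLR had a low steer in 3 of the 4 groups, at 7.95 in ISeNTE 28, 9.08 in ISeTE 18 and 8.65 in MIXNTE 32, with nearest values of 9.32, 10.2 and 9.64. RBM3 was high in MIXNTE 32 (10.3) and MIXTE 34 (9.73), MCL1 in ISeTE 3 (9.70), LOC782385 in ISeTE 3 (5.11), CIDEA in ISeNTE 28 (5.55) and OR7E203 in ISeTE 24 (4.14). Low values were GPX3 in MIXTE 15 (8.71), KIZ in ISeTE 22 (6.34), LRRC66 in MIXTE 23 (4.02), DNAI3 in ISeNTE 5 (3.88) and DPPA3 in MIXNTE 26 (3.22).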

How the results depend on the processing

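The covariates of the first principal component and the interferon score, the counts at an unadjusted p, and quantile normalisation for single genes, were chosen after seeing the data. The count of 0 probe sets was the same in all 7 contrasts with quantile normalisation, array weights, trended and robust moderation, no moderation, 1 probe set per gene and each covariate, and in the 4 differences between single groups with fits of 16 arrays. For the endophyte it became 4 among probe sets above the median level and 4 at an adjusted p of 0.10. Leaving out each array gave 0 to 5 for the endophyte, with 5 without MIXNTE 19 and 1 without ISeNTE 20, ISeNTE 28 or MIXTE 34, and 0 to 1 within MIX, with 1 without MIXTE 7. Counts at an unadjusted p under 0.05 among probe sets above the median level were 1469 for the endophyte, 178 for the selenium form and 334 for the interaction, and 386 for the selenium form with 1 probe set per gene, where fewer probe sets were tested.

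The gene lists called (10, 5 and 9 for the endophyte, the selenium form and the interaction) fell to 0, 0 and 0 with an estimated correlation and to 0, 0 and 0 with fry. With genes above the median level they were 6 and 2 for the endophyte and the selenium form, with the chromaffin score as a covariate 3 and 0 of 32 lists (9 and 5 of which were called without it), and with the interferon score 6 and 5 of 33 lists for the endophyte and the interaction (9 and 8 without it). For the selenium form the interferon score gave 5 calls, 3 of them among the 4 without it and 2 others. For the interaction the chromaffin score gave 9 calls, the 8 without it and 1 other. Apart from fewer genes in the filtered test, the cause was not tested. No called list turned its direction under these settings. With genes above the median level the interaction had 9 calls, 6 of them among the 9 before. Leaving out 1 array gave 3 to 11, 0 to 8 and 4 to 11 lists. For the endophyte there were 3 without ISeNTE 11, 5 without ISeNTE 5 and 6 without ISeTE 1, MIXTE 4, MIXTE 17, ISeTE 24 or MIXNTE 25. For the selenium form there were 8 without ISeTE 1, 0 without MIXTE 4, 1 without MIXNTE 13 or MIXNTE 32, 2 without ISeTE 3, ISeTE 6, MIXNTE 14, MIXTE 15, MIXTE 17, MIXTE 23, ISeTE 24 or MIXNTE 26, and 3 without ISeNTE 8, ISeNTE 11, MIXTE 12, ISeTE 18, ISeNTE 20 or MIXTE 29. For the interaction there were 4 without ISeNTE 10, 5 without MIXNTE 32 and 6 without MIXTE 7 or ISeNTE 20. The endophyte calls of the NRF2 and fibroblast lists and the interaction calls of immediate early and cell cycle genes were not lost without any 1 array. Cell cycle was lost without ISeNTE 11 for the endophyte (adjusted p = 0.057) and without MIXTE 4 or ISeNTE 11 for the selenium form (up to 0.18), chromaffin markers without ISeTE 1 or ISeNTE 11 for the endophyte (up to 0.057), heat shock without ISeNTE 10 for the interaction (0.052) and unfolded protein response without ISeTE 1 or ISeNTE 10 (up to 0.062). The other called lists were each lost without 3 to 21 of the arrays.

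Of 90 named gene values, 88 kept their sign and 2 turned with quantile normalisation, CYP11A1 for the endophyte to 0.0029 and SELENOP for the interaction to -0.011, and the other probe set of CYP21A2 gave 0.0098 for the interaction. All 3 were near 0 and none was called. Signal over background was not known, so limits for dim genes were not set. A log transform of linear values was not run, because the values are log2 already.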

Other observations

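The tests below were chosen after seeing the per-steer values, except the correlation of the 2 endophyte differences, whose test was fixed before its result was seen.

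Interferon genes were high in the same 8 steers, spread over all 4 groups: ISeNTE 5, 11 and 20, ISeTE 3 and 6, MIXNTE 25, and MIXTE 7 and 34. IFI44, an interferon-induced gene, lay between 8.13 and 9.78 on the log2 scale in these steers and between 4.95 and 6.62 in the other 24, and MX1, an antiviral GTPase gene, between 10.7 and 12.3 against 6.95 to 9.34. The 8 highest values of MX1, OAS1Y, HERC6 and ISG15 were in those 8 steers. No group held more than 3 of them. A further steer, ISeNTE 10, lay between the ranges for ISG15, at 7.53 against at most 6.55 in the steers below it. Its MX1, at 9.34, was the highest of the lower range, while its IFI44, at 6.14, lay within the lower range.

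GSTA5, a glutathione transferase gene, also fell into 2 separate ranges, with 18 steers between 5.80 and 8.53 and 14 between 10.97 and 12.53. The higher range held 4 ISeNTE, 3 ISeTE, 5 MIXNTE and 2 MIXTE steers. RPL15, a ribosomal protein gene, lay between 9.58 and 10.04 in 8 steers and between 7.65 and 8.22 in the other 24, and 1 of the 8 was among the steers with high interferon genes. No explanation of these ranges was tested.

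A hypothesis tested here is that the endophyte shifts the same genes under both selenium forms. The TE minus NTE differences within ISe and within MIX share no steers, and across 18087 genes, which are not independent replicates, they correlated at 0.29. In a one-sided count, 2 of 100 splits of the MIX steers gave a correlation as high, the real one included, with the highest other at 0.31 and the lowest at -0.25. The MIX minus ISe differences within TE and within NTE correlated at -0.04, with 75 of 100 splits as high. The first value is consistent with a small endophyte difference shared by both forms. Pasture, sampling order or any handling that followed the endophyte in both forms could give the same value, and no label used here separates them.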
